A study of Homo sapiens with 6 samples.

How the data were processed

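Transcripts were counted from their 3' ends in A549, an established human lung carcinoma cell line, after 48 h in medium with 25 mM glucose or in medium without it, with 3 libraries per group. Per the labels' protocols, first-strand cDNA was primed with barcoded oligo-dT, libraries were pooled by the Actb signal in quantitative PCR, and the pool was amplified for 12 PCR cycles to give strand-specific libraries. Pooling by 1 transcript sets each library's share of the reads, and the shares are removed by the library scaling used below. The protocol mentions no molecular identifiers, so PCR copies are counted as separate reads, and every interval or floor given here covers counting error only. The protocol does not say how RNA was extracted, and nothing in the labels says that the libraries of a group came from separate cultures.

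The deposited table holds raw counts of reads per gene for the 6 libraries, made by the authors with STAR and HTSeq on genome build hg19, per the submitters' processing notes. The versions of these tools, the gene annotation and the strand setting of the counting are not given in the sources used here. Genes are listed by Entrez identifier. Of 19240 genes, 19178 were matched to a symbol through a RefSeq gene table of assembly GRCh38.p14, which was used for names only; the 62 without a symbol held 0.0072% of the gene counts. Because the builds differ, no coordinates are given. The 5 HTSeq summary lines name no gene and stayed out of library sizes and tests. Reads outside any gene made up 32.8% to 36.5% of each library, reads with more than 1 alignment 18.4% to 22.2%, and ambiguous reads 0.369% to 0.419%. Between 43.1% and 44.7% of the reads in the table fell in genes. Reads that align equally well to near-identical genes or pseudogenes belong to the set left out of the gene counts, so values of such genes are uncertain.

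Gene counts per library were 6701004, 10323290 and 14259943 with glucose and 11086416, 12782563 and 14060313 without glucose, for replicates 1, 2 and 3. The most abundant gene, HSP90AA1, took 1.03% to 1.50% of the gene counts of a library. No count in any library was seen for 4354 genes. A count of 0 over a group was read as a level below 3 counts.

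Libraries were assigned to groups from their labels. The groups were compared with the quasi-likelihood F test of edgeR 4.0.16 (two-sided) on the deposited counts, with TMM scaling, filterByExpr at its minimum count of 10, no covariate, and Benjamini-Hochberg adjustment over the 11886 genes kept; an adjusted p under 0.05 passed. Errors of log2 fold changes, given as SE, are the size of the log2 fold change divided by the square root of its F statistic. They were thus worked back from the test and are approximate. Levels are CPM, counts relative to the scaled library size, computed here. The SE of a list median comes from the spread over its genes, treated as independent. For some genes with few counts in a group, the ratio of pooled counts relative to the scaled library totals (gene totals times the TMM factors) is given with an exact 95% interval. Others have the fitted log2 fold change alone. Gene lists were compared with all other tested genes by camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists with at least 3 tested members. Camera with a correlation estimated from the data, and fry, which asks whether the genes of a list move on balance one way, were run beside it.

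The groups, the tests, the 29 gene lists (4 primary and 25 other), the rule for named genes and the alternatives were fixed before the data were examined. Of 721 list entries, 707 were matched; GDF15 and SESN2 stand in both the ATF4 and the p53 list and MDH2 in both the anaplerosis and the tricarboxylic acid cycle list, and these are the only overlaps. The list of mitochondrially encoded subunits was not analysed here. The rule names PCK2 and PCK1; the 10 genes with the highest and the 10 with the lowest log2 fold change among those that passed, had a mean of 20 or more counts per library and had groups whose CPM did not overlap; the 4 members of each primary list and the 3 of each other list with the smallest p. Members that did not pass, in lists that did not pass, could be left out. Some genes that the rule names are not reported here. Other genes named in the text were chosen after their values were seen.

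To see whether a library had been deposited more than once, the libraries of a group were compared by a chi-square test of their counts over genes. The statistic divided by its degrees of freedom was 23.0 to 60.0, above sampling noise, so no libraries were merged; this does not show that they came from separate cultures. The labels do not say that replicate numbers mark a shared culture, day or batch, so the test had no replicate block. Same-numbered libraries did not deviate together either, though 3 libraries per group are too few to show whether the numbers pair them.

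The alternatives were RLE scaling, library totals without scaling factors, no filter on low counts, a mean of at least 20 counts per library, the replicate number as a block, each library left out in turn, DESeq2 1.42.0 in place of edgeR, and both other list tests. Trends of log2 fold change with GC content over the last 500 bases and with transcript length were removed with splines of 4 degrees of freedom, using the longest GENCODE transcript of each gene on GRCh38. The code was tested on counts simulated for these groups with 200 changed genes, of which those among the 11766 genes that passed the filter were scored. For the comparison without against with glucose, edgeR recovered 4.08% of genes changed 1.5-fold, 36.0% of those changed 2-fold, 97.9% at 4-fold and 100% at 8-fold, and 4.20% of its calls were unchanged genes. DESeq2 recovered 8.16%, 48.0%, 97.9% and 97.9%, with 12.9% of calls unchanged. In the real data a larger share of genes passed (22.3%), so these rates need not hold there. In a second simulation over 11760 genes, a list raised 1.5-fold was the only list called of 27 tested. Genes were drawn independently of each other there. It therefore does not show how often unchanged lists whose genes vary together would be called. R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.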

Results

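The series asked how tumor cells adapt to growth without glucose, and its title names PCK2, the mitochondrial phosphoenolpyruvate carboxykinase. A549 lung carcinoma cells were held for 48 h with 25 mM glucose or without glucose, and 3 libraries per group were counted from transcript 3' ends. Libraries held 6701004 to 14259943 gene counts with glucose and 11086416 to 14060313 without it. The libraries of a group are not stated to be separate cultures, so p-values measure only the spread between these libraries, which may be technical. The first principal component held 57.4% of the variance and separated the groups. The second held 17.6% and set replicate 1 with glucose (score 38.6) apart from replicates 2 and 3 (−23.9 and −19.9). The libraries without glucose also spread along it, with scores of −19.3, 20.2 and 4.25 for replicates 1, 2 and 3.

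Without glucose, genes of the unfolded protein response rose together and genes of DNA replication and mitosis fell together. HSPA5, the main chaperone of the endoplasmic reticulum, went from 773 ± 139 to 6874 ± 1665 CPM (mean ± SD, n = 3 per group). TK1, the thymidine kinase of dividing cells, went from 126 ± 1.16 to 26.1 ± 1.15 CPM. PCK2 rose 3.53-fold. Glycolysis genes as a list were lower at the preset correlation but not with an estimated one (adjusted p = 0.458), and 3 of them rose. Immediate-early and heat-shock genes, listed beforehand as a check for handling stress, were higher in the same libraries (median log2 fold change 0.63). Again the list did not pass with an estimated correlation (adjusted p = 0.335). Whether handling or the absence of glucose raised these genes was not tested. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 1376 genes were higher and 1276 lower without glucose, together 22.3% of the 11886 tested. Of the genes tested, 4800 (40.4%) had groups whose CPM did not overlap, against 10% by chance for 3 against 3 libraries. The number of higher genes was 860 without replicate 2 with glucose, 894 without replicate 3 with glucose and 870 without replicate 3 of the cells without glucose. Leaving out that last library gave 781 lower genes.

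**Figure D1:**
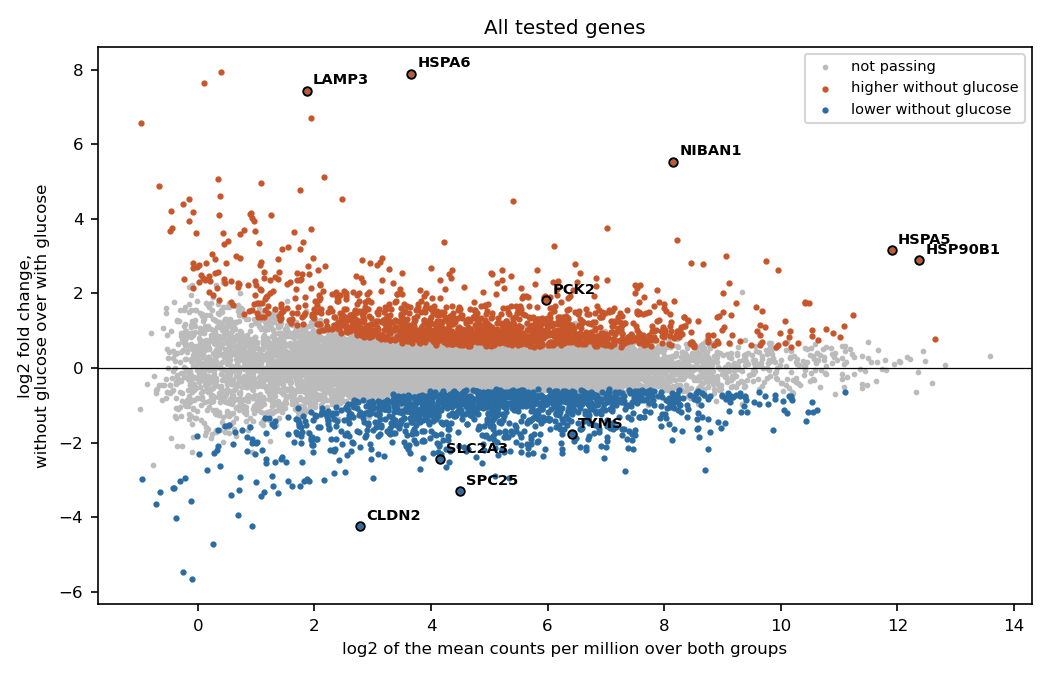
Each point is 1 of 11886 tested genes, with the log2 of its mean CPM over both groups on the horizontal axis and its log2 fold change, without over with glucose, on the vertical axis; orange points are the 1376 genes that rose, blue points the 1276 that fell and grey points those that did not pass. HSPA5 and HSP90B1 lie among the abundant genes at log2 fold changes of 3.15 and 2.89, while CLDN2 lies at −4.23.

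PCK2 (Entrez 5106), which turns oxaloacetate into phosphoenolpyruvate in mitochondria, rose from 27.8 ± 5.60 to 97.8 ± 6.21 CPM (SD, n = 3 per group). Its log2 fold change was 1.82 ± 0.21 (SE), with an adjusted p of 1.82e-04 by the edgeR quasi-likelihood test. All 3 libraries without glucose lay above all 3 with glucose. PCK1, the cytosolic form of the enzyme, had a count of 0 in each of the 6 libraries, below the floor of 3 counts. FBP1 and G6PC1, which catalyze the late steps of gluconeogenesis, were likewise at 0. Of 11 tested genes of gluconeogenesis and anaplerosis, 3 rose and 8 did not pass, and adjusted over the list alone 3 also rose. The list as a whole did not pass (median log2 fold change 0.11, camera adjusted p = 0.110). Its median was 0.35 without replicate 1 with glucose, 0.30 and 0.21 without replicates 1 and 3 of the cells without glucose, and 0.06 with library totals as scaling. GOT1, the cytosolic aspartate aminotransferase, rose with a log2 fold change of 1.58 ± 0.19. ME2, the mitochondrial malic enzyme, rose by 0.62 ± 0.20, a call that missed the threshold with either other scaling, with no filter on low counts, and on leaving out any library but replicate 1 with glucose (adjusted p from 0.0517 to 0.155). The related ME3 had a log2 fold change of 0.51 ± 0.21 and did not pass.

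Glycolysis genes were lower on balance, and the glucose carriers and hexokinase moved in different directions. Of 23 tested members 3 rose, 8 fell and 12 did not pass; adjusted over the list alone, 3 rose and 10 fell. SLC2A3, a high-affinity glucose transporter, fell with a log2 fold change of −2.44 ± 0.25. PGAM1, the phosphoglycerate mutase, and LDHA, which makes lactate from pyruvate, fell with log2 fold changes of −1.19 ± 0.22 and −0.75 ± 0.18. HK2, an inducible hexokinase, rose from 9 counts over the libraries with glucose to 138 without, a ratio of 13.1 relative to scaled library totals (95% interval 6.69 to 29.2); without replicate 2 with glucose it had 3 counts there (ratio 26.3, 8.82 to 129). SLC2A1, the common glucose transporter, and SLC16A1, a lactate and pyruvate carrier, also rose, by 0.84 ± 0.21 and 0.74 ± 0.22 on the log2 scale. The median log2 fold change of the list was −0.31 (camera adjusted p = 0.0392; adjusted p = 0.458 with an estimated correlation). The call was lost without replicate 1 with glucose (adjusted p = 0.101, median −0.19) and without replicate 1 of the cells without glucose (0.0892). With a replicate block the list call was also lost (camera adjusted p = 0.0708), as was the call for LDHA (edgeR adjusted p = 0.0505). The number of members that fell was 5 without replicate 1, and also without replicate 3, of the cells without glucose; the median was −0.46 without replicate 2 with glucose, where 1 member rose, as it did without replicate 3 with glucose.

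Genes of serine synthesis and one-carbon metabolism moved in both directions. Among 19 tested members 4 rose, 5 fell and 10 did not pass; adjusted over the list alone, 5 rose and 5 fell. TYMS, the thymidylate synthase, fell with a log2 fold change of −1.76 ± 0.20. ALDH1L2, a mitochondrial folate enzyme, rose from 12.1 ± 1.55 to 62.3 ± 37.3 CPM. CBS, the first enzyme of transsulfuration, rose by 1.65 ± 0.23 on the log2 scale. PHGDH, which starts serine synthesis from a glycolytic intermediate, rose 2.32-fold. As a list the genes did not pass (median log2 fold change 0.21, camera adjusted p = 0.987), and 3 members fell when any library but replicate 1 or 3 with glucose was left out. The median was 0.07 to 0.13 without replicate 2 or 3 of either group.

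Targets of ATF4, the transcription factor of the amino acid stress response, were mostly higher without glucose. Of 26 tested genes 14 rose, 2 fell and 10 did not pass, with the same numbers adjusted over the list alone. CEBPG, a partner of ATF4, rose with a log2 fold change of 1.91 ± 0.22. DDIT3, which encodes the stress factor CHOP, rose by 1.70 ± 0.22 and NUPR1, a stress-induced nuclear protein, by 1.53 ± 0.21. ADM2, a secreted peptide, rose from 0.930 ± 0.419 to 6.93 ± 0.298 CPM. The members that fell were CHAC1, a glutathione-degrading enzyme, and ATF5, a related transcription factor (log2 fold changes −2.11 and −0.91); without replicate 3 of the cells without glucose, 1 member fell. The ATF4 transcript had a log2 fold change of 0.00 and did not pass. The list had a median log2 fold change of 0.71 (camera adjusted p = 7.73e-05; adjusted p = 0.0975 with an estimated correlation). The correlation estimated for the ATF4 list was 0.015, near the preset one, so correlated genes alone hardly account for the higher p. The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose in 7 of 20 cases and fell in 1, or 8 and 1 adjusted over the list alone. No synthetase fell with a replicate block or on leaving out any library but replicate 2 of the cells without glucose. Those for tryptophan (WARS1), glycine (GARS1) and serine (SARS1) had log2 fold changes of 2.22 ± 0.20, 1.53 ± 0.20 and 1.45 ± 0.21. That list passed with a median of 0.31 (camera adjusted p = 0.0392; adjusted p = 0.289 with an estimated correlation). It did not pass without replicate 1 with glucose (0.0841), replicate 2 with glucose (0.0810) or replicate 1 of the cells without glucose (0.0510), and its median was 0.17 without either replicate 1.

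The unfolded protein response had the highest median of the 28 lists tested, a log2 fold change of 2.02 over 25 tested genes. Of these, 22 rose and 3 did not pass, and 23 rose adjusted over the list alone (camera adjusted p = 1.83e-33). CRELD2, a secreted stress protein of the endoplasmic reticulum, rose 13.5-fold, from 18.0 ± 2.89 to 243 ± 29.5 CPM. HSPA5 rose 8.89-fold, with a log2 fold change of 3.15 ± 0.24. PDIA4, a protein disulfide isomerase, rose 6.18-fold. HYOU1 and HSP90B1, chaperones of the same compartment, had log2 fold changes of 3.43 and 2.89. XBP1 and ATF6, transcription factors of the response, rose by 0.98 and 1.24. PDIA3, SEC61B and ERN1 did not pass. With an estimated correlation, only this list (adjusted p = 0.0226) and both cell cycle lists (0.0226 and 0.0227) passed.

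Enzymes that build sugar nucleotides and N-glycan precursors rose in 9 of 26 cases, and adjusted over the list alone 11 rose and 1 fell. GFPT1, which controls entry into the hexosamine pathway, had a log2 fold change of 1.35 ± 0.20. GMPPA, a regulatory subunit of GDP-mannose synthesis, and UAP1, which makes UDP-GlcNAc, rose by 1.27 ± 0.22 and 1.16 ± 0.21. The median was 0.43 (camera adjusted p = 0.00322; adjusted p = 0.246 with an estimated correlation). Autophagy and lysosome genes rose in 9 of 35 cases, also 9 adjusted over the list alone. WIPI1, which acts at forming autophagosomes, rose from 10.4 ± 2.65 to 63.9 ± 8.20 CPM. MAP1LC3B and GABARAPL1, of the ubiquitin-like proteins that coat autophagosomes, had log2 fold changes of 1.47 ± 0.20 and 1.52 ± 0.23. Here the median was 0.41 (camera adjusted p = 3.05e-04; adjusted p = 0.289 with an estimated correlation).

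Cell cycle genes fell together. Of 32 tested genes of the G1/S transition and DNA replication, 30 fell and 2 did not pass, and all 32 fell adjusted over the list alone (median log2 fold change −1.71, camera adjusted p = 1.87e-35). TK1 fell with a log2 fold change of −2.28 ± 0.19, RRM2, a subunit of ribonucleotide reductase, with −2.16 ± 0.20, and MCM4, of the replicative helicase, with −2.15 ± 0.21. Of 30 genes of G2 and mitosis, 28 fell and 2 did not pass, and all 30 fell adjusted over the list alone (median −1.32, camera adjusted p = 1.03e-22); when 1 library was left out, 20 to 29 fell. The mitotic kinases PLK1 and AURKA had log2 fold changes of −2.06 ± 0.20 and −2.40 ± 0.25, and KIF20A, a kinesin of cytokinesis, −2.28 ± 0.23. Targets of p53, which restrains the cell cycle, rose in 6 of 24 cases, the same adjusted over the list alone (median 0.52, camera adjusted p = 0.0218; adjusted p = 0.289 with an estimated correlation). CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 1.19 ± 0.21, and the death receptor genes TNFRSF10B and FAS by 1.11 ± 0.24 and 1.22 ± 0.30 on the log2 scale. The p53 list did not pass without replicate 3 with glucose (0.0520) or replicate 2 of the cells without glucose (0.0539). FAS did not pass without replicate 2 with glucose (0.0560) or replicate 3 of the cells without glucose (0.0659). Only 2 p53 targets rose without replicate 2 with glucose, and 3 without replicate 3 of either group.

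**Figure D2:**
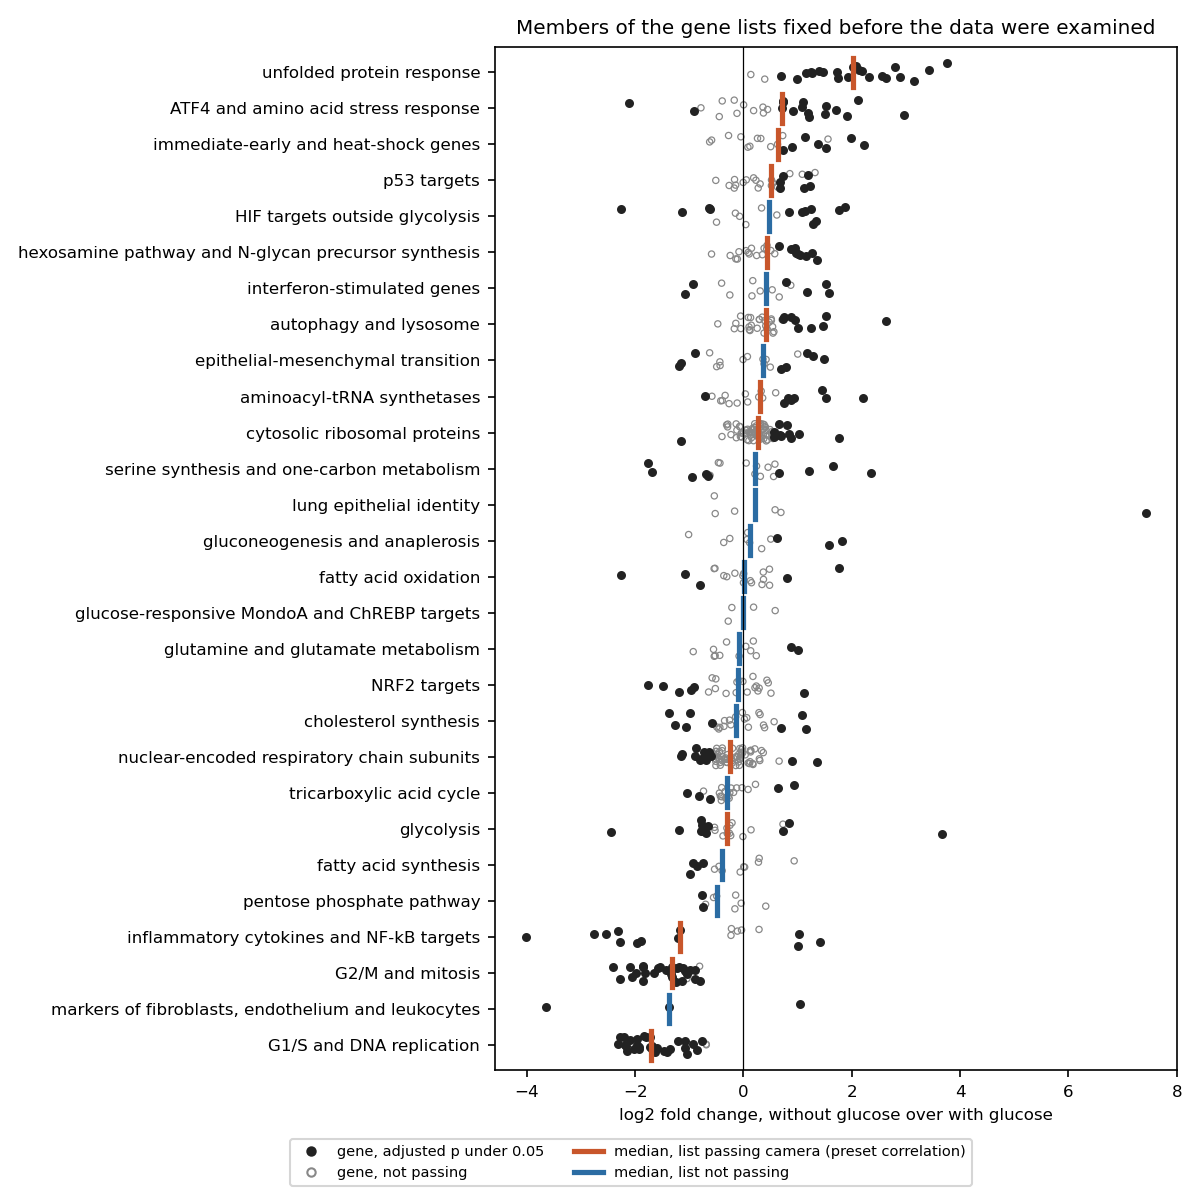
Each point is the log2 fold change, without over with glucose, of 1 tested member of a list named on the vertical axis, filled where the gene passed; bars mark list medians, orange where the list passed camera at the preset correlation. The unfolded protein response lies at the top with a median of 2.02 and the G1/S list at the bottom with −1.71.

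Of the inflammatory genes under NF-kB, the transcription factor of inflammation, more fell than rose without glucose. Of 17 tested, 3 rose, 9 fell and 5 did not pass, the same adjusted over the list alone. The chemokine genes CXCL1, CCL2 and CXCL8, which attract leukocytes, had log2 fold changes of −2.28 ± 0.24, −1.96 ± 0.23 and −1.89 ± 0.24. NFKB2, RELB and IL11 were the members that rose. The median was −1.16 (camera adjusted p = 2.64e-04; adjusted p = 0.305 with an estimated correlation), but −0.69 over genes with a mean of at least 20 counts and −0.23 over the 21 members tested with no filter on low counts. Interferon-stimulated genes rose in 4 of 14 cases and fell in 2, or 6 and 2 adjusted over the list alone, and did not pass as a list (median 0.42, camera adjusted p = 0.266). OAS3 and OAS1, which sense double-stranded RNA, fell with log2 fold changes of −0.94 ± 0.18 and −1.09 ± 0.27, and IRF9, of the interferon signaling complex, rose by 1.53 ± 0.30. OAS1 did not pass without replicate 3 of the cells without glucose (0.0590). Without replicate 2 or 3 with glucose 1 of the interferon-stimulated genes rose, and without replicate 2 or 3 of the cells without glucose 2 rose; the median was 0.71 without replicate 1 with glucose, 0.27 without replicate 2 and 0.64 without replicate 3 of the cells without glucose, where 1 fell.

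Among respiratory chain genes of mitochondria, more fell than rose, but most did not pass. Of 72 nuclear-encoded subunits 2 rose, 11 fell and 59 did not pass, and adjusted over the list alone 2 rose and 9 fell. The ATP synthase subunit genes ATP5MC3, ATP5MF and ATP5MC1 fell with log2 fold changes of −1.14 ± 0.20, −1.14 ± 0.24 and −0.90 ± 0.21. The list passed with a median of −0.26 (camera adjusted p = 0.0120; adjusted p = 0.470 with an estimated correlation; median −0.14 after trends with GC content and transcript length were removed), but not without replicate 1 of the cells without glucose (0.0510). The number of subunits that fell was 4 without replicate 3 with glucose, 5 without replicate 1 of the cells without glucose, and 7 without replicate 2 with glucose or replicate 3 without it, and the number that rose was 0 to 2. Of 22 tricarboxylic acid cycle genes 2 rose and 3 fell, the same adjusted over the list alone (median −0.30, camera adjusted p = 0.110). SDHA, of succinate dehydrogenase, fell with −1.05 ± 0.19, and SUCLG2, of succinyl-CoA synthetase, rose by 0.94 ± 0.20. FH, the fumarase, fell with −0.63 ± 0.19, but did not pass when any library was left out (adjusted p from 0.0523 to 0.0943). In that list 1 gene rose and 1 fell without replicate 2 or 3 of either group, and 1 rose without replicate 1 with glucose.

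Glutamine and glutamate genes rose in 2 of 13 cases, while adjusted over the list alone 2 rose and 4 fell (median −0.08, camera adjusted p = 0.745). PYCR1, of proline synthesis, rose by 1.02 ± 0.20 and the glutamine carrier SLC38A1 by 0.89 ± 0.21, the latter not without replicate 3 of the cells without glucose (0.0563). The median of that list ran from −0.29 to 0.20 when 1 library was left out, and with library totals as scaling it was −0.14 and 2 members fell. Pentose phosphate genes fell in 2 of 9 cases, and 4 adjusted over the list alone (median −0.49, camera adjusted p = 0.110). PGD, the 6-phosphogluconate dehydrogenase gene, and TKT, the transketolase, fell with −0.77 ± 0.20 and −0.74 ± 0.19. Neither passed without replicate 3 of the cells without glucose (0.0767 and 0.0677), nor PGD without replicate 2 (0.0817) and TKT without replicate 3 (0.0837) with glucose. The number that fell was at most 1 with a replicate block and without replicate 3 of the cells without glucose or replicate 2 or 3 with glucose, and it was 4 without replicate 2 of the cells without glucose and with library totals as scaling.

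Lipid genes moved in both directions. Cholesterol synthesis genes rose in 3 of 25 cases and fell in 5, or 4 and 5 adjusted over the list alone (median −0.14, camera adjusted p = 0.385). EBP, a sterol isomerase, fell with a log2 fold change of −1.37 ± 0.22, while MSMO1, a sterol oxidase, rose by 1.16 ± 0.20. On leaving out any library but replicate 2 with glucose, 3 members fell, and the median ran from −0.23 to −0.01 when 1 library was left out. Fatty acid synthesis genes fell in 4 of 13 cases, and adjusted over the list alone 1 rose and 5 fell (median −0.39, camera adjusted p = 0.110). FADS2, a desaturase, SREBF1, a lipid transcription factor, and FASN, the fatty acid synthase, had log2 fold changes of −0.93 ± 0.19, −0.86 ± 0.21 and −0.99 ± 0.25. FASN did not pass without replicate 2 or 3 with glucose (0.0534 and 0.0566), and the list median was −0.14 without replicate 2 with glucose and −0.24 without replicate 3 of the other group. Fatty acid oxidation genes rose in 2 of 20 cases and fell in 3, the same adjusted over the list alone. PDK4, a kinase that restrains pyruvate oxidation, fell with −2.26 ± 0.23, HADH, an oxidation enzyme, fell with −1.09 ± 0.21, and ANGPTL4, a secreted lipase inhibitor, rose by 1.77 ± 0.29. For that list the median was 0.00, with the mean (−0.06) and the test (camera adjusted p = 0.619) below 0, and the median was −0.06 with library totals as scaling and ran from −0.07 to 0.10 when 1 library was left out. In that list 1 gene rose without replicate 1 or 2 with glucose or replicate 3 of the other group.

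Hypoxia-factor targets outside glycolysis rose in 8 of 18 cases and fell in 4, or 9 and 4 adjusted over the list alone (median 0.48, camera adjusted p = 0.0539). NDRG1, a stress-responsive gene, BNIP3L, a receptor for mitophagy, and LOXL2, a collagen cross-linking enzyme, rose by 1.87 ± 0.23, 1.76 ± 0.22 and 1.34 ± 0.20. The list passed with no filter on low counts (0.0494), without replicate 1 with glucose (also 0.0494) and without replicate 2 (0.0368) or 3 (0.0451) of the cells without glucose. On leaving out these 3 libraries, or replicate 2 with glucose, 2 members fell. NRF2 targets, of the antioxidant response, rose in 1 of 24 cases and fell in 5, or 1 and 6 adjusted over the list alone (median −0.10, camera adjusted p = 0.110). GPX2, a glutathione peroxidase, ALDH3A1, an aldehyde dehydrogenase, and AKR1C2, an aldo-keto reductase with near-identical relatives, fell with −1.76 ± 0.22, −1.48 ± 0.22 and −1.20 ± 0.19. The NRF2 list passed without replicate 2 of the cells without glucose (0.0485, median −0.16). Of the list for the glucose-sensing factors MondoA and ChREBP, 4 members were tested and did not pass, also adjusted over the list alone. Among them was MLXIP, the gene of MondoA itself (log2 fold change 0.19 ± 0.20), so the list does not hold targets alone. That list had a median of −0.01, with the mean (0.07) and the test (camera adjusted p = 0.803) above 0, and the median ran from −0.13 to 0.17 when 1 library was left out. TXNIP and ARRDC4, its best-known glucose-induced members, had 5 and 1 counts over the libraries with glucose and 9 and 2 without, too few to test.

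Among cytosolic ribosomal protein genes, more rose than fell, but most did not pass. Of 78 tested 11 rose, 1 fell and 66 did not pass, and adjusted over the list alone 9 rose and 1 fell (median 0.27, camera adjusted p = 0.0183; adjusted p = 0.428 with an estimated correlation). RPL12 and RPL26 rose by 1.76 ± 0.32 and 1.02 ± 0.22, and RPS26 fell with −1.14 ± 0.19; these genes have many processed pseudogenes, so their counts are uncertain. Without replicate 2 or 3 with glucose 3 and 2 genes rose, and without replicate 2 or 3 of the cells without glucose 6 and 3.

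Among immediate-early and heat-shock genes 7 of 19 rose, and adjusted over the list alone 9 rose and 2 fell (median 0.63, camera adjusted p = 0.0107; adjusted p = 0.335 with an estimated correlation). HSPA1B, a cytosolic heat-shock protein gene with a near-identical copy in HSPA1A, had a log2 fold change of 1.53 ± 0.24, and the immediate-early factors JUN and EGR1 had 1.37 ± 0.27 and 1.99 ± 0.39; without replicate 3 with glucose 4 members rose. Genes of epithelial-mesenchymal transition rose in 5 of 19 cases and fell in 3, or 6 and 3 adjusted over the list alone (median 0.36, camera adjusted p = 0.745). KRT8, an epithelial keratin, and CCN2, a matrix-associated growth factor, fell with −1.18 ± 0.20 and −1.16 ± 0.23. In that list 2 rose without replicate 2 with glucose, and 3 and 1 without replicates 1 and 3 of the cells without glucose. Of 6 tested lung epithelial genes, LAMP3 rose and 5 did not pass, with 2 that rose adjusted over the list alone (median 0.21, camera adjusted p = 0.213); the median was 0.01 without replicate 3 with glucose, 0.12 without replicate 1 or 2 of the other group, −0.16 over genes with a mean of at least 20 counts, and 0.57 with no filter on low counts. Of 19 markers of fibroblasts, endothelium and leukocytes 3 were tested, of which 1 rose and 2 fell, the same adjusted over the list alone (median −1.37, camera adjusted p = 0.237; −0.16 over the 2 with a mean of at least 20 counts). COL1A1, a fibrillar collagen, fell with −1.37 ± 0.25, and CD68, also a lysosomal protein of many cells, rose by 1.04 ± 0.22. CD14, a monocyte receptor, went from 36 to 3 counts, a ratio of 0.0710 (95% interval 0.0140 to 0.225).

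Over all genes, those that rose the most included several with almost no reads in glucose. NIBAN1 (Entrez 116496), a stress-responsive regulator of translation and survival, rose from 12.0 ± 1.85 to 556 ± 16.3 CPM (log2 fold change 5.53 ± 0.24, adjusted p = 1.57e-07). HSPA6, an inducible heat-shock protein gene with a near-identical pseudogene, went from 3 counts to 960, a ratio of 273 relative to scaled library totals (95% interval 93.1 to 1325). LAMP3, a lysosomal membrane protein gene, went from 1 count to 269 (ratio 229, 40.8 to 9090), and RPS6KA2, a ribosomal S6 kinase gene, from 2 to 287 (122, 33.6 to 1015); these counts with glucose all lay in replicate 3, without which each gene was at least 42.2-fold higher, taking the floor of 3 counts over the libraries left with glucose. BEX2, of a family of small brain-expressed proteins, rose from 3.59 ± 1.26 to 81.4 ± 16.3 CPM, and its relative BEX4 from 14 counts to 400. Of the 14 counts 12 lay in replicate 2, without which BEX4 had 2 counts with glucose (ratio 114, 95% interval 31.5 to 949). PRDM16, a transcription factor of brown fat, rose by 4.77 ± 0.56 on the log2 scale, from 7 counts to 246 (ratio 30.0, 95% interval 14.3 to 75.3). Of the 7 counts 4 lay in replicate 1 with glucose. TMIE, a gene of inner-ear hair cells, rose by 4.15 ± 0.58, from 6 counts to 131 (ratio 18.6, 95% interval 8.3 to 51.6). CDH15, a muscle cadherin, rose by 5.13 ± 0.76, but its 7 counts with glucose all lay in replicate 1. Without that library the ratio at the same floor was 71.9, with an exact 95% lower limit of 58.2. CHST1, a keratan sulfate sulfotransferase, rose by 4.97 ± 0.84, with 4 counts in replicate 3 with glucose. Without that library its ratio at the same floor was 23.7, with an exact 95% lower limit of 19.0.

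CLDN2, which forms cation pores in tight junctions, had the lowest log2 fold change among the named genes and went from 13.0 ± 2.43 to 0.694 ± 0.297 CPM. SPC25, of the kinetochore, fell from 40.9 ± 9.46 to 4.15 ± 0.931 CPM. H1-3, a linker histone gene of a family of close copies, fell with a log2 fold change of −4.23 ± 0.83; without replicate 3 with glucose, which held 99 of its 133 counts there, the ratio was 0.0968 (95% interval 0.0362 to 0.222). The potassium channel gene KCNJ16 (−3.43 ± 0.51), the intermediate filament gene NES (−3.35 ± 0.51) and the focal adhesion gene TNS4 (−3.33 ± 0.68) also fell; TNS4 had 4 counts without glucose when replicate 2 of that group was left out (ratio 0.0373). So did DIRAS3, an imprinted Ras-like gene (−3.18 ± 0.52), SLFN13, an RNase (−3.17 ± 0.43), and GRHL3, an epithelial transcription factor (−3.17 ± 0.49). PDE3A, a cyclic nucleotide phosphodiesterase, fell with −3.04 ± 0.76; without replicate 2 of the cells without glucose it had 115 counts with glucose and 2 without (ratio 0.0229, 95% interval 0.00274 to 0.0845), and the call was lost without replicate 2 with glucose (adjusted p = 0.0670) and without replicate 3 of the other group (0.0523).

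**Figure D3:**
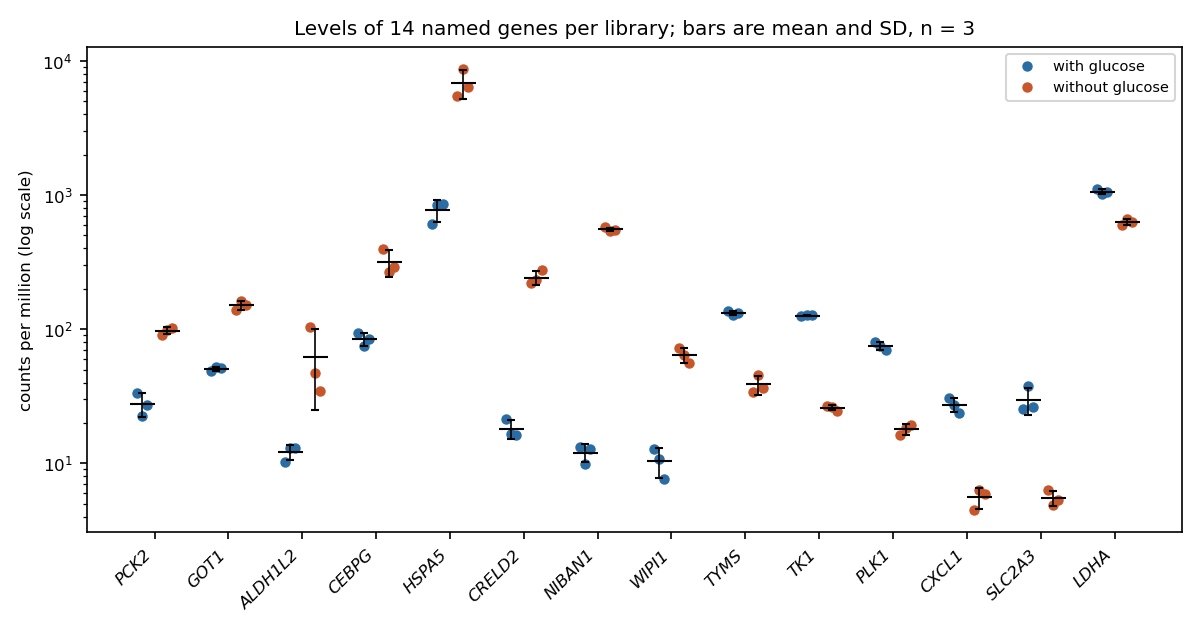
CPM of 14 named genes on a log axis, with 1 point per library and bars for the mean and SD of 3 libraries per group. The groups do not overlap for any of the genes drawn, which were picked from genes named mostly for a small p or a large fold change. HSPA5 went from 773 to 6874 CPM and TK1 from 126 to 26.1 CPM.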

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

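The calls over 2-fold and the p53 list without the genes it shares with the ATF4 list were chosen after the results were seen. Between 2610 and 3122 genes passed in total under RLE scaling, library totals, both other filters and DESeq2, against 2652, and in none of the alternatives did a shared call have the opposite sign. DESeq2 gave 1541 higher and 1581 lower genes, and 2650 of the 2652 calls were shared. The share of calls that were higher was 51.9% with TMM, 49.6% with RLE and 45.2% with library totals. Same-numbered libraries correlated at −0.27, −0.12 and 0.04 in their deviations from the group means. These values are too few to show whether the numbers pair the samples. With a replicate block 984 genes were higher and 911 lower. Under that block the glycolysis list had a camera adjusted p of 0.0708, as did the aminoacyl-tRNA synthetases. LDHA, ME2, FH, PGD and TKT then missed the threshold. Leaving out 1 library gave 860 to 1292 higher and 781 to 1232 lower genes; the cause was not tested beyond the smaller group. Requiring more than a 2-fold change left 796 higher and 681 lower genes, by construction. PCK2 passed throughout, with log2 fold changes of 1.68 to 1.97 when 1 library was left out. For the glycolysis list, leaving out 1 library gave adjusted p from 0.0260 to 0.101. With an estimated correlation the glycolysis and ATF4 lists had 0.458 and 0.0975, and 3 of the 24 other lists passed instead of 11. Among the lists that lost the call, the estimated correlation ran from 0.015 (synthetases) to 0.20 (glycolysis). For the synthetase, ATF4 (0.015) and p53 (0.021) lists it lay near the preset one, so correlated genes alone hardly account for those losses. What else raised these p-values was not tested. By fry, which does not compare a list with other genes, gluconeogenesis and anaplerosis had 0.0229 and 19 other lists passed. Without the shared genes the p53 list had an adjusted p of 0.0152. Of the 99 named genes that passed, 89 passed in each alternative run and 10 did not in at least 1. The alternative without mitochondrially encoded genes was not run, since no such gene was tested. Depth limits the genes with few counts in 1 group, whose ratios span wide intervals, and in simulated data most 1.5-fold changes went uncalled.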

Other observations

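The gene lists of the next paragraph were chosen after the table of all genes had been seen; the tests in the later paragraphs were fixed before their results were seen.

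The rise of endoplasmic reticulum genes reached beyond chaperones. Of 29 genes for translocation into the endoplasmic reticulum and for glycan transfer, 16 rose (median log2 fold change 0.65, camera adjusted p = 3.46e-06; adjusted p = 0.0159 with an estimated correlation), among them SSR1, of the translocon-associated complex, with 1.77 ± 0.23. Of 22 genes for COPII export, 5 rose (median 0.40, camera adjusted p = 0.0171; adjusted p = 0.288 with an estimated correlation), and of 19 for degradation from the endoplasmic reticulum 5 rose and 2 fell (0.294). Of 23 homologous recombination and Fanconi anemia genes, 17 fell (median −1.20, camera adjusted p = 6.30e-13; adjusted p = 0.0159 with an estimated correlation), among them EXO1, an exonuclease, with −2.02 ± 0.23. Wnt feedback targets fell in 4 of 10 cases (median −0.36, camera adjusted p = 1.14e-04; adjusted p = 0.0406 with an estimated correlation): DKK1, a secreted Wnt inhibitor, went from 288 ± 10.2 to 63.5 ± 15.3 CPM, and AXIN2 fell with −3.02 ± 0.43. Plasma proteins of hepatocyte type, which A549 is known to secrete, fell in 4 of 8 cases (median −1.19, camera adjusted p = 1.76e-04; adjusted p = 0.0406 with an estimated correlation), among them the fibrinogen chain gene FGB with −2.89 ± 0.33. The camera p-values of these lists were adjusted over the lists of this paragraph alone. They can therefore not be ranked against the adjusted p-values of the lists fixed beforehand. As these lists were built from the same table, their p-values are descriptions and not independent evidence.

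TXNIP, a gene known to be strongly induced by glucose, had few counts in both groups: 0, 2 and 3 counts in the libraries with glucose and 1, 5 and 3 in those without, so no difference was detectable at this depth. Whether this reflects the culture, the annotation or the position of its 3' end was not tested. HSPA6, by contrast, had 1 count in each library with glucose and 159, 396 and 405 without, while the constitutive HSPA8 had a log2 fold change of −0.27 and did not pass.

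The 25 unfolded protein response genes were higher with a median log2 fold change of 2.02. After trends with GC content and transcript length were removed the median was 1.99 (SE 0.25), so neither trend accounts for the rise. With each library thinned to the smallest gene total the median was 2.04 (SE 0.24). Thinning leaves the expected fold changes of well-counted genes unchanged. The thinned median could thus hardly have moved and does not decide whether depth plays a part. A biological response to the absence of glucose stays open; what in the cells would drive it was not tested, and cell density and medium exhaustion at 48 h were not measured and stay open too. Of the 10 splits of the 6 libraries into 3 and 3, only the labelled one (1 split) gave as many calls by edgeR, 2652 against at most 0 in the others (4334 against at most 701 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05.

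The joint median of the G1/S and G2/M genes was −1.56, and it was also −1.56 (SE 0.09) after trends with GC content and length were removed. With the 100 most abundant genes and the unfolded protein response list taken out and library totals as scaling it was −1.53 (SE 0.10), which argues against a few abundant genes as the cause. Bulk libraries do not separate a smaller share of cycling cells from lower transcription in each cell, and no test of either was run.

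For the small shifts in mitochondria and ribosomes, the same correction moved the respiratory chain median from −0.26 to −0.14 (SE 0.05) and the ribosomal protein median from 0.27 to 0.35 (SE 0.04). GC content and length thus do not account for the ribosomal protein median, which moved away from 0 on correction. The respiratory chain median moved toward 0, so a part of that shift may come from these trends. Its SE treats the genes as independent, while their estimated correlation was 0.18, so the SE is likely too small. Whether the corrected respiratory chain median differs from 0 therefore cannot be told here. Reads shared with ribosomal protein pseudogenes were not tested.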
